A study of Homo sapiens with 6 samples.

How the data were processed

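RNA was sequenced from FaDu cells, an epithelial line from a human squamous carcinoma of the pharynx, 48 h after treatment with TGF-β or a mock treatment. There were 3 control samples (replicates 2, 3 and 4) and 3 TGF-β samples (replicates 2, 3 and 4), grouped by the labels. The TGF-β isoform and its dose are not given in the sources used here. Total RNA was isolated with a column kit and libraries were made with a directional kit, per the labels' protocols. Whether the counting used the strand is not given in the sources used here, so a gene and an overlapping antisense partner cannot be told apart.

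HISAT2 2.1.0, Bowtie2 2.2.4 and genome build hg19 are named, per the submitters' processing notes, with no role or order. The counting tool and the annotation are not given in the sources used here. The authors deposited 1 table of 57773 genes with a column of normalized signal per sample, the mean signal over samples, and the columns of a DESeq2 comparison, per the file headers. The sample signal deposited by the authors is a gene count divided by 1 size factor per sample, as the values themselves show: in each column 100% of values are whole multiples of the smallest positive value, within a tolerance of 1e-06 reads. The log2 fold changes and their standard errors were computed by the authors, per the file headers. Their sign is that of TGF-β against control, as the values themselves show. The test score deposited by the authors has the header that DESeq2 gives its test statistic, which does not name the kind of test. The deposited p-value and adjusted p-value columns are those of the same DESeq2 comparison, per the file headers. From the authors' deposited table only counts of calls are quoted here. Coordinates are those of the table, build hg19.

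Whole reads were recovered by dividing each column by its smallest positive value. They summed to between 119851680 and 148133320 reads in genes per sample, and 32906 to 34483 genes had at least 1 read. Genes with 2 reads (2514 to 2659 per sample) outnumbered genes with 1 read (1839 to 2063), so the number of independent fragments is below the number of reads. The genes RN7SL1, RN7SL2 and RN7SK together took between 9.46% and 14.8% of the normalized values of a sample, and genes of the mitochondrial chromosome between 0.0128% and 0.0160%. Pairs of replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom from 34.4 to 98.8, so no library was treated as a duplicate. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

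The test planned before the data were examined was edgeR's quasi-likelihood test for raw counts, with limma-trend named as the main test if the table held values divided by size factors. The table held such values, so limma 3.58.1 (R 4.3.3) was fitted to log2(value + 1) with the group as the only term, an intensity trend and Benjamini-Hochberg adjustment at 0.05. Genes entered with a normalized count of at least 10 in at least 3 samples, which left 23645 genes. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. edgeR 4.0.16, DESeq2 1.42.0 and limma-voom were run on the recovered reads as alternatives. On simulated data with 200 changed genes among 23645 for this comparison, repeated 3 times, limma recovered 26.7% of 1.3-fold, 42.7% of 1.5-fold, 63.3% of 2-fold and 91.3% of 4-fold changes when the dispersion followed the trend, and 3.72% of its calls were false. With a dispersion for each gene it recovered 12.0%, 34.7%, 57.3% and 84.0%, and 11.0% of its calls were false, above the nominal rate. The simulation drew each gene independently and held no variation shared between genes. These rates may therefore not carry over to samples in which genes vary together.

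Fixed before the data were examined were 37 gene lists, with 967 entries, of which 7 were matched by another symbol, 2 by gene identifier and 1 was not matched. Each list was tested with camera (preset correlation 0.01, two-sided, adjusted over the 37 lists), and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Genes named in the text follow a rule fixed at the same time: the 15 largest rises and 15 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, the 4 members of each list with the smallest p, and a fixed set of 16 genes. The text takes them from the top of each part, and SPARC, TGFB1, SMAD2, SMAD3, TGFBR1 and the genes of blood cells and of chromosome 18 around SMAD4 were chosen after their values were seen. Some genes that the rule names are not reported here.

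Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a CPM of at least 1 in at least 3 samples, TMM, library size and upper quartile scaling, a replicate block, the count tools, and leaving out each sample in turn. DESeq2 size factors are the scaling of the deposited values. Added after seeing the data were a leukocyte marker score as a covariate, a fit without the 2 libraries lowest and highest in leukocyte markers, and edgeR with TMM on the recovered reads. Figures were drawn with matplotlib 3.10.9.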

Results

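The transcriptome of FaDu cells was measured by sequencing of total RNA in 3 mock-treated control samples and 3 samples treated with TGF-β, a cytokine that signals through SMAD proteins, all taken at 48 h. The samples held 119851680 to 148133320 reads in genes. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.990 and 0.993 within groups and between 0.986 and 0.992 across groups. The first principal component held 31.4% of the variance and placed all 3 control samples below all 3 TGF-β samples. Set beside an index of leukocyte markers (mean of the 6 libraries = 1), control replicate 3 was lowest on both (-48.4 and an index of 0.583), TGF-β replicate 4 was highest on both (41.2 and 1.38), and within each group both gave the same order. The comparison asks which genes differ between TGF-β and mock treatment.

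After TGF-β, 12 of 30 TGF-β feedback and direct target genes rose and 1 fell, and 11 of 35 unfolded protein response and ATF4 target genes rose. Interferon-stimulated genes fell in 24 of 45 members, simple epithelial keratins in 5 of 7 and epithelial junction and identity genes in 8 of 40. These lists were called by camera with a preset correlation, while 0 of 37 lists was called with an estimated correlation (lowest adjusted p = 0.211). PMEPA1, which encodes a feedback inhibitor of TGF-β signalling, rose from 7512 ± 689 to 30382 ± 1172 normalized counts (SD, n = 3), a 4.04-fold change. KRT8, a keratin of simple epithelia, fell from 218074 ± 19174 to 89750 ± 1722 normalized counts. OASL, an interferon-stimulated gene, fell from 19749 ± 1597 to 6713 ± 562 normalized counts. Of 23645 genes tested, 937 changed at an adjusted p under 0.05 (limma), 330 higher and 607 lower, and 154 of them changed at least 2-fold, 54 higher and 100 lower. The authors' deposited table held 1245 genes with an adjusted p under 0.05, of which 927 were called here in the same direction. The limma count of called genes was 419, 874 and 554 without control replicates 2, 3 and 4. It was 489, 463 and 618 without TGF-β replicates 2, 3 and 4. A leukocyte marker score as a covariate, added after seeing the data, gave 1570 genes, 707 higher and 863 lower. With a replicate block limma called 2595 genes, 1387 higher and 1208 lower, though no label pairs the samples.

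**Figure D1:**
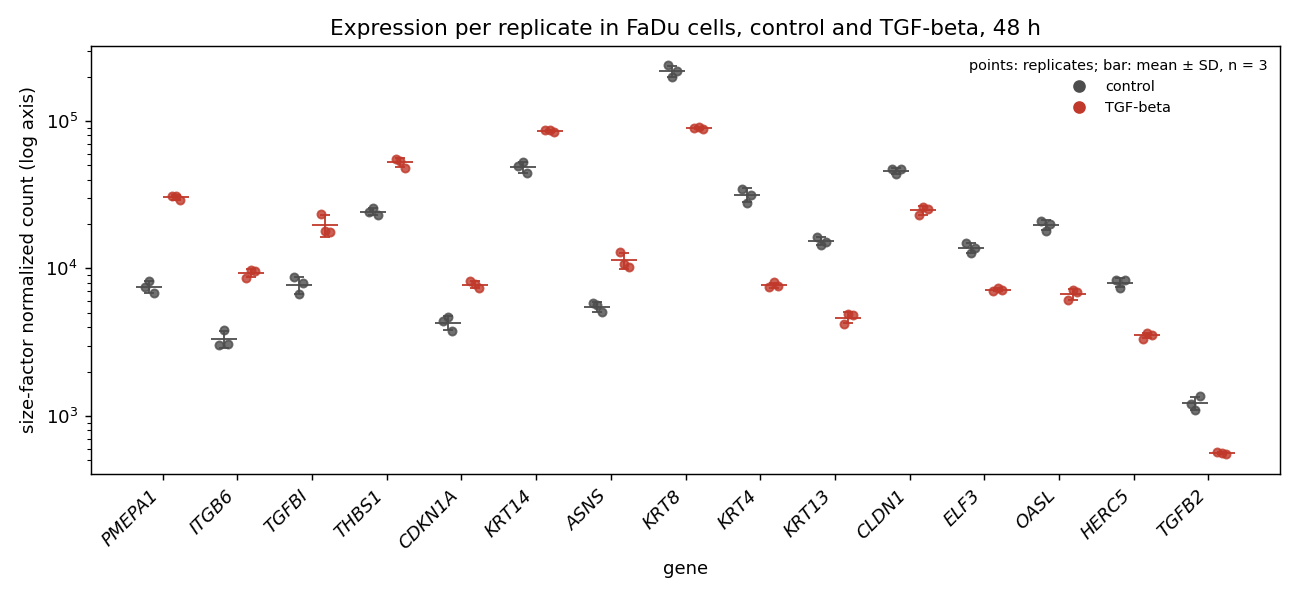
Size-factor normalized counts (log axis) of 15 genes per replicate, control in grey and TGF-β in red, with the mean ± SD (n = 3). For each gene the 3 TGF-β values lie on one side of the 3 control values, for example PMEPA1 from 7512 to 30382 and KRT8 from 218074 to 89750 in the group means.

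Among the 15 largest rises, ADAMTS15, an extracellular metalloprotease, had a log2 change of 2.33 ± 0.12 (SE, limma adjusted p = 5.64e-05). CREG2 rose by 1.97, CST6, a cysteine protease inhibitor, by 1.76, and AMIGO2, an adhesion protein, by 1.22 on the log2 scale. ITGB6, the integrin subunit of the receptor αvβ6 that activates latent TGF-β, rose by 1.49 and the cytokine gene IL11 by 1.47. The amino acid transporter gene SLC7A8 rose by 1.22 and WISP2, a matricellular protein gene, by 1.15. Among the 15 largest falls, the cytochrome P450 gene CYP2W1 fell by 2.07, VGLL1, a TEAD cofactor gene, by 1.99 and AMOT, an angiomotin gene, by 1.89 on the log2 scale. Ceruloplasmin (CP) fell by 1.73, MACC1 by 1.33 and CCDC80 by 1.32. The semaphorin gene SEMA3E fell from 2898 ± 56.2 to 1177 ± 56.9 normalized counts (SD, n = 3).

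TGF-β feedback and direct target genes formed a group of 30 tested members, of which 12 rose, 1 fell and 17 were not called (15 and 2 adjusted over the list alone). PMEPA1 (ENSG00000124225, chromosome 20, 56223448 to 56286592, hg19) had a log2 change of 2.02 ± 0.07 (SE, limma adjusted p = 1.88e-05). TGFBI rose by 1.33 and THBS1, thrombospondin 1, by 1.11 on the log2 scale, and IGFBP3 fell by 0.87. The list was higher by camera (adjusted p = 8.49e-11), with an adjusted p = 0.211 with an estimated correlation. TGFB1, a member of this list, had a log2 change of 0.45 (limma adjusted p = 0.248), and its relation to the leukocyte markers missed the threshold (exact permutation, adjusted p = 0.0519). SMAD7, an inhibitory SMAD gene, had a log2 change of 0.22 (limma adjusted p = 0.186).

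Of 28 genes for TGF-β superfamily ligands, receptors and SMADs, 1 rose and 5 fell (1 and 10 adjusted over the list alone). The ligand gene TGFB2 fell by 1.12 and BMP7 by 0.54 on the log2 scale, the receptor gene TGFBR2 fell by 0.23, and FSTL3, which encodes a ligand-binding inhibitor, rose by 0.94. The list was lower by camera (adjusted p = 0.00336, and adjusted p = 0.211 with an estimated correlation). SMAD4, the common SMAD gene, was measured at 491 ± 181 and 624 ± 161 normalized counts (SD, n = 3), against a mean of 14760 for SMAD2, and its relation to the leukocyte markers missed the threshold too (exact permutation, adjusted p = 0.0519). Its log2 change was 0.40 (limma adjusted p = 0.515), with 0.0436 without control replicate 3, 0.19 without TGF-β replicate 4 and 0.61 without control replicate 4. No member of the 11 tested BMP-SMAD target genes was called (camera adjusted p = 0.228).

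Simple epithelial keratins fell: 5 of 7 tested members were lower and 0 were higher (the same counts adjusted over the list alone). KRT8 (ENSG00000170421, chromosome 12, 53290977 to 53343738) fell by 1.28, KRT18 by 1.08, KRT19 by 0.86 and KRT7 by 0.35 on the log2 scale. The spans of KRT8 and KRT18 overlap on opposite strands, so reads in the overlap are uncertain. The camera adjusted p was 9.92e-07, and adjusted p = 0.211 with an estimated correlation. Among 31 squamous differentiation genes, 3 rose and 6 fell (4 and 7 adjusted over the list alone) and the list was not called (camera adjusted p = 0.314, and 0.0372 with the leukocyte score as a covariate). KRT4, a keratin of mucosal squamous epithelium, fell from 31451 ± 3421 to 7701 ± 307 normalized counts (SD, n = 3), its partner KRT13 fell by 1.72 and KLF4 by 0.72 on the log2 scale. CALML3 had a log2 change of 2.44, with an overlapping antisense gene that makes its reads uncertain. Of 16 basal keratinocyte genes, 2 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.228), and its median of 0.15, its mean of 0.01 and camera were higher while fry was lower. Camera called that list higher with the leukocyte score as a covariate (adjusted p = 8.32e-04), without the 2 libraries lowest and highest in leukocyte markers (6.38e-04), without control replicate 3 (0.0226) and without TGF-β replicate 4 (0.0339). KRT14 rose by 0.82, while KRT15 fell by 1.17 and NGFR by 0.96 on the log2 scale.

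Of 40 epithelial junction and identity genes, 8 fell and 0 rose (13 and 0 adjusted over the list alone). The tight junction genes CLDN1 and TJP3 fell by 0.89 and 0.92 on the log2 scale, the epithelial transcription factor gene ELF3 by 0.93 and MAL2 by 0.50. The camera adjusted p was 1.31e-07, and adjusted p = 0.415 with an estimated correlation. CDH1, E-cadherin, had a log2 change of -0.26 (limma adjusted p = 0.0839).

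Among 16 EMT transcription factors, ETS1 rose by 0.36 and SNAI2 by 0.26 on the log2 scale, and the other 14 were not called (the same counts adjusted over the list alone, camera adjusted p = 0.118). SNAI1 was measured at 22.0 and 35.2 normalized counts in control and TGF-β samples, ZEB1 at 156 and 194, ZEB2 at 932 and 1154 and TWIST1 at 469 and 419, with limma adjusted p from 0.361 to 0.515. Of 27 mesenchymal and motility genes, 6 rose and 2 fell (9 and 3 adjusted over the list alone). CD44 rose by 0.59, tenascin C (TNC) by 0.76 and fibronectin (FN1) by 0.47 on the log2 scale, while the WNT inhibitor gene DKK1 fell by 0.44 and FSTL1 by 0.38. The list was higher by camera (adjusted p = 0.0324), with an adjusted p = 0.263 with an estimated correlation and 0.139 with a CPM of at least 1. VIM, vimentin, had a log2 change of 0.44 (limma adjusted p = 0.375) and CDH2, N-cadherin, of 0.12 (adjusted p = 0.479). VIM and SPARC varied between libraries with the leukocyte markers, and for ZEB2 that relation missed the threshold (exact permutation, adjusted p = 0.0778).

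Collagens and their modifying enzymes were higher by camera (adjusted p = 0.00456, and adjusted p = 0.211 with an estimated correlation): 5 of 31 rose and 3 fell (6 and 3 adjusted over the list alone). COL5A1 rose from 1523 ± 115 to 3070 ± 495 normalized counts (SD, n = 3). COL7A1, the anchoring fibril collagen, rose by 0.84 and COL4A2, whose span overlaps that of COL4A1, by 0.46 on the log2 scale, and LOXL4, a collagen cross-linking enzyme gene, fell by 0.83. Of 31 extracellular proteases and inhibitors, 6 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.0567). That list was called higher without control replicate 3 (adjusted p = 0.0332), without TGF-β replicate 2 (0.0174), without the 2 libraries extreme in leukocyte markers (0.0496), with the leukocyte score as a covariate (0.0371), under library size (0.0400) and upper quartile scaling (0.0465) and by fry (0.0424). The collagenase gene MMP13 rose by 0.67, TIMP3 by 0.68 and ADAM12 by 1.07, and the kallikrein gene KLK10 fell by 0.63. Of 14 integrins, ITGB5 and ITGA2 rose by 0.47 and 0.46 and ITGB8 fell by 0.71 on the log2 scale (the same counts adjusted over the list alone, camera adjusted p = 0.0977, and 0.0230 without control replicate 3, 0.0368 with the leukocyte score as a covariate and 0.0336 without the 2 libraries extreme in leukocyte markers). Actin contractile and focal adhesion genes were higher by camera (adjusted p = 9.92e-07, and adjusted p = 0.218 with an estimated correlation), with 4 of 34 rising and 0 falling (14 and 0 adjusted over the list alone). Myosin light chain kinase (MYLK) rose by 0.89, LIMA1 by 0.40 and tropomyosin 4 (TPM4) by 0.27.

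Interferon-stimulated genes fell: 24 of 45 were lower and 0 were higher (28 and 0 adjusted over the list alone), with a median log2 change of -0.39. OASL (ENSG00000135114, chromosome 12, 121458095 to 121477045) fell by 1.56, HERC5, the ligase of the ubiquitin-like protein ISG15, by 1.19, the helicase gene DDX60 by 1.09 and DDX58, which encodes the RNA sensor RIG-I, by 0.86. The camera adjusted p was 6.99e-25, and adjusted p = 0.311 with an estimated correlation of 0.65 between members. Of 14 tested MHC class I and antigen presentation genes, the peptidase genes ERAP2 and ERAP1 fell by 0.40 and 0.32 and 0 rose (the same counts adjusted over the list alone). That list was not called (camera adjusted p = 0.356, lower, although its median log2 change was 0.02 and its mean 0.08), but it was called lower with the leukocyte score as a covariate (adjusted p = 0.00335) and without the 2 libraries extreme in leukocyte markers (0.00200). For HLA-C, a member of it, the relation to the leukocyte markers missed the threshold (exact permutation, adjusted p = 0.0519). Of 37 cytokine and NF-kB target genes, 3 rose and 5 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.0588). That list was called lower with the leukocyte score as a covariate (adjusted p = 0.00346), without the 2 libraries extreme in leukocyte markers (0.00164), without control replicate 3 (0.0134), without TGF-β replicate 4 (0.0132) and under library size scaling (0.0458). The complement gene C3 fell by 0.90 and BIRC3 by 0.75, while IL24 rose by 1.02 and PTGS2, a prostaglandin synthase gene, by 0.71.

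Unfolded protein response and ATF4 target genes rose in 11 of 35 members and 0 fell (17 and 0 adjusted over the list alone). Among genes of amino acid supply, asparagine synthetase (ASNS) rose by 1.04, the serine synthesis gene PSAT1 by 0.83 and the cystine transporter gene SLC7A11 by 0.56 on the log2 scale. NUPR1, a stress response gene, rose by 1.10. The camera adjusted p was 1.82e-09, and adjusted p = 0.218 with an estimated correlation. Hypoxia and glycolysis genes rose in 9 of 34 members and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.18e-08, and adjusted p = 0.311 with an estimated correlation). NDRG1 rose by 0.82, DDIT4 by 0.60 and the lactate transporter gene SLC16A3 by 0.37.

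Of 34 cholesterol and fatty acid synthesis genes, MSMO1 and FDFT1 rose by 0.28 and 0.25 and 0 fell (8 and 1 adjusted over the list alone). The list was higher by camera (adjusted p = 0.00116), with an adjusted p = 0.467 with an estimated correlation and 0.0633 without control replicate 4. Of 26 NRF2 target genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.104, and 0.0485 without control replicate 2), with GCLM up by 0.38 and ALDH3A1 at a log2 change of -0.84. Of 24 AP-1 and immediate early genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone). SPHK1 rose by 0.88 and the ERK phosphatase gene DUSP6 by 0.50, while DUSP5 fell by 0.48. The camera adjusted p was 0.0137, and adjusted p = 0.467 with an estimated correlation and 0.0538 without control replicate 4. Of 23 YAP-TEAD target genes, 4 fell and 0 rose (5 and 1 adjusted over the list alone), with CRIM1 at a log2 change of -0.42 and AMOTL2 at -0.36. Their camera adjusted p was 0.0324, with an adjusted p = 0.467 with an estimated correlation, 0.242 with the leukocyte score as a covariate, 0.314 without the 2 libraries extreme in leukocyte markers, 0.0895 without control replicate 3 and 0.115 without TGF-β replicate 4.

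G1/S and DNA replication genes had a median log2 change of -0.12, with 40 of 42 members below 0. CDC25A, a cell cycle phosphatase gene, fell by 0.34 and was the only called member (0 and 8 adjusted over the list alone), and E2F1 and MCM2 had log2 changes of -0.27 and -0.22. The list was lower by camera (adjusted p = 5.25e-08, and adjusted p = 0.467 with an estimated correlation). No member of the 46 G2/M genes was called, with a camera adjusted p = 0.0324, higher, and an adjusted p = 0.610 with an estimated correlation. That call was lost under library size scaling (adjusted p = 0.104), under upper quartile scaling (0.0918) and without any 1 of control replicates 2 and 4 and TGF-β replicates 2 and 3 (0.0999 to 0.423). DNA repair genes were lower by camera (adjusted p = 1.61e-04, adjusted p = 0.470 with an estimated correlation, 0.134 with the leukocyte score as a covariate and 0.245 without the 2 libraries extreme in leukocyte markers), and BARD1 fell by 0.19 as the only called member of 36 (0 adjusted over the list alone). Among 7 CDK inhibitors (camera adjusted p = 0.444, the same counts adjusted over the list alone), CDKN1A, which encodes p21, rose from 4273 ± 452 to 7774 ± 426 normalized counts (SD, n = 3) and CDKN2C fell by 0.41. MYC fell by 0.31 and ODC1 rose by 0.30 among 30 MYC and ribosome biogenesis genes (the same counts adjusted over the list alone, camera adjusted p = 0.444). That list was called higher with the leukocyte score as a covariate (adjusted p = 0.00857) and without the 2 libraries extreme in leukocyte markers (0.0151). PLK2 fell by 0.83 as the only called member of 25 p53 target genes (2 and 3 adjusted over the list alone, camera adjusted p = 0.339, and 0.0397 by fry).

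**Figure D2:**
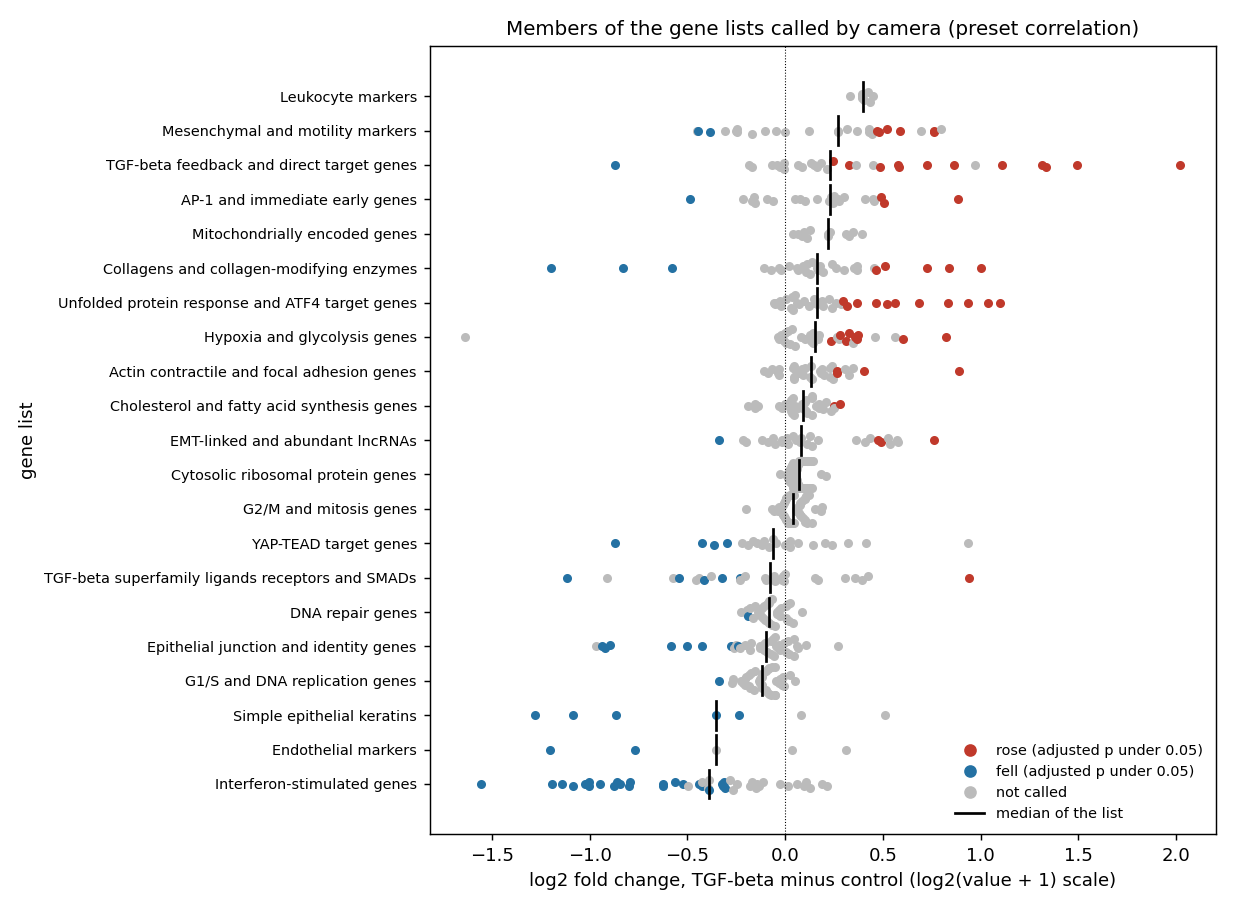
Log2 fold change (TGF-β minus control, log2(value + 1) scale) of each tested member of the 21 gene lists called by camera with the preset correlation; red points rose and blue points fell at an adjusted p under 0.05, grey points were not called, and the black line is the median of the list. Interferon-stimulated genes lie lowest, with a median of -0.39, and 24 of 45 members fell.

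Of 25 stem-like and squamous carcinoma regulators, 1 rose and 6 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.0548). The list was called lower under TMM (adjusted p = 0.0390), library size (0.0448) and upper quartile scaling (0.0465), without control replicate 4 (0.0398) and without TGF-β replicates 2 (0.0400) and 3 (0.0227). The aldehyde dehydrogenase gene ALDH1A3 rose by 0.54, and the growth factor receptor genes FGFR3 and ERBB3 fell by 0.50 and 0.35 on the log2 scale. Among 29 EMT-linked and abundant lncRNAs, 3 rose and 1 fell (4 and 1 adjusted over the list alone). LINC00941 rose by 0.76 and MIR22HG by 0.49, and H19 fell by 0.34 (camera adjusted p = 0.00821, and adjusted p = 0.218 with an estimated correlation).

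Markers of other cell types were measured in the same libraries. The 8 leukocyte markers were present in every library, and CD74 was measured at 58668 ± 18279 and 76989 ± 15393 normalized counts (SD, n = 3). No leukocyte marker was called by limma, all 8 had log2 changes above 0 with a median of 0.40, and the list was higher by camera (adjusted p = 0.00821, and adjusted p = 0.470 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.0950) and without TGF-β replicate 4 (adjusted p = 0.0662), the libraries lowest and highest in these markers. A straight line of VIM on the leukocyte marker index left -2.29% of its mean level at an index of 0, against 102% for SMAD2, and SPARC, ZEB2, TGFB1, HLA-C and SMAD4 left between -15.2% and 14.4%. Over the 6 libraries r with the index was 0.992 for VIM and 0.999 for SPARC (exact permutation p = 0.00139, adjusted p = 0.0194 for each), with a Spearman's rho of 1 (p = 0.00278, adjusted p = 0.0389). It was 0.990 for HLA-C, 0.985 for SMAD4 and 0.973 for TGFB1 (exact permutation p = 0.00556, 0.0111 and 0.0111, adjusted p = 0.0519 for each) and 0.948 for ZEB2 (p = 0.0208, adjusted p = 0.0778), and for these 4 rho lay between 0.829 and 0.943 (p from 0.0167 to 0.0583, adjusted p from 0.156 to 0.204). The adjustment was over 28 genes chosen after values were seen, without 4 blood-cell markers that follow the index by construction or choice. Without the 2 libraries farthest from the median r was 0.975 for VIM, 0.999 for SPARC, 0.809 for HLA-C, 0.675 for SMAD4, 0.554 for TGFB1 and 0.399 for ZEB2. The libraries left span an index of only 0.929 to 1.10, and r of the erythroid marker HBB fell there from 0.986 to 0.744. For SMAD4, TGFB1 and ZEB2 the relation is thus shown mainly by the 2 libraries left out. The drop cannot tell a weak relation from a narrow range of the index. Of 5 tested endothelial markers, CDH5 fell from 725 ± 40.0 to 314 ± 14.7 normalized counts (SD, n = 3) and VWF fell by 0.77 on the log2 scale (the same counts adjusted over the list alone). That list was lower by camera (adjusted p = 0.0171), with an adjusted p = 0.442 with an estimated correlation, 0.0709 without control replicate 4 and 0.0523 without TGF-β replicate 2. FBLN1 fell by 0.43 as the only called member of 5 fibroblast markers (the same count adjusted over the list alone, camera adjusted p = 0.401).

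**Figure D3:**
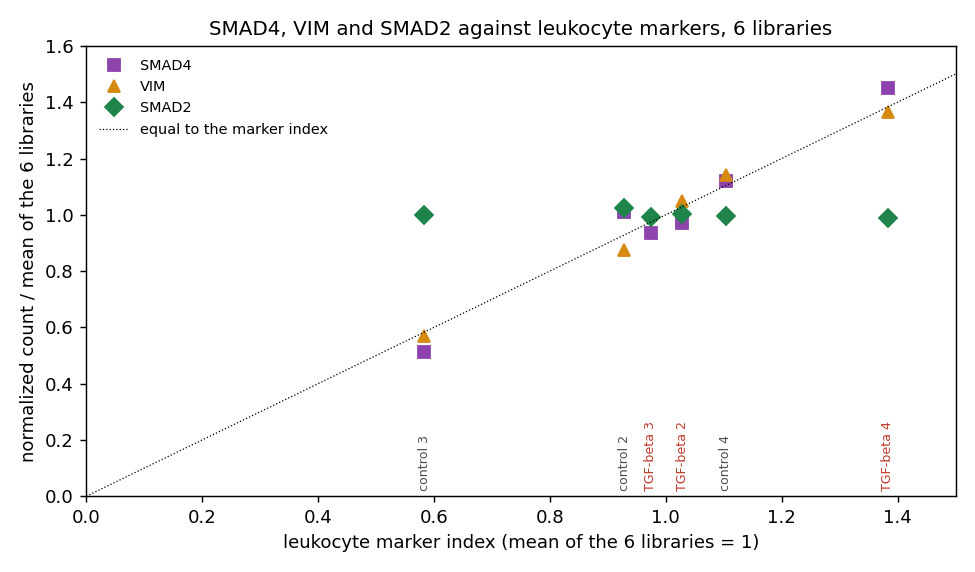
Normalized count of SMAD4, VIM and SMAD2 relative to its mean over the 6 libraries, against the leukocyte marker index of the library (mean of the 6 libraries = 1), with the line of equality dotted. The index runs from 0.583 in control replicate 3 to 1.38 in TGF-β replicate 4, and SMAD4 and VIM lie near the line while SMAD2 stays near 1.

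The 13 mitochondrially encoded genes had a median log2 change of 0.22 and 0 were called, while camera gave an adjusted p = 0.00466, with an adjusted p = 0.470 with an estimated correlation and 0.102 with the leukocyte score as a covariate. Of 53 cytosolic ribosomal protein genes, 52 had a log2 change above 0, with a median of 0.07, and 0 were called (camera adjusted p = 2.63e-06, and adjusted p = 0.470 with an estimated correlation). Replication-dependent histone genes (camera adjusted p = 0.0977) and housekeeping genes (camera adjusted p = 0.0787) had 0 called members, and 2 housekeeping genes rose adjusted over the list alone. The histone list was called lower without control replicate 4 (adjusted p = 0.0250) and without TGF-β replicate 3 (0.0497), and the housekeeping list higher without control replicate 2 (0.0236), without TGF-β replicate 4 (0.0339), with the leukocyte score as a covariate (0.0368) and without the 2 libraries extreme in leukocyte markers (0.0451). Of the 7 lists with 0 called members by limma, the members at an unadjusted p under 0.05 numbered 2 for BMP-SMAD targets, 3 for G2/M genes, 0 for leukocyte markers, 4 for mitochondrially encoded genes, 9 for ribosomal protein genes, 3 for histone genes and 4 for housekeeping genes. By edgeR, DESeq2 and limma-voom on the recovered reads 0 members of these lists were called, except 1, 1 and 2 ribosomal protein genes and 1 housekeeping gene by limma-voom. With an estimated correlation 0 of the 37 lists was called by camera (7 at an unadjusted p under 0.05), against 21 with the preset correlation and 14 by fry, and 3833 single genes had an unadjusted limma p under 0.05.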

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

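The leukocyte score covariate, the fit without the 2 libraries lowest and highest in leukocyte markers, and edgeR with TMM were chosen after seeing the data. Over pseudocounts, filters, scalings and tools the number of called genes lay between 676 (library size scaling) and 1255 (DESeq2), apart from the replicate block and edgeR without a filter (1758, with 702 higher and 1056 lower), and all 118 named called genes kept their direction in all 22 alternatives. With a CPM of at least 1 the genes changed at least 2-fold numbered 102, with fewer genes tested. Whether replicate numbers pair the samples stays open, as no label says so. The deviations of same-numbered samples correlated at 0.0703, 0.362 and 0.472, and those of different numbers at -0.467 to 0.185. Replicates 3 and 4 of each group correlated best with their own number, while replicates 2 did not. Reads in genes had the same order of replicate numbers in both groups (lowest 2, highest 3), and so had the leukocyte index (lowest 3, highest 4). The share of RN7SL1, RN7SL2 and RN7SK was highest in replicates 2 of both groups, but replicates 3 and 4 differed in order. With a replicate block limma called 2595 genes (1387 higher, 1208 lower) and edgeR 2623 (1223 higher, 1400 lower), which is a hint from the data and not from the design. With the leukocyte score as a covariate 1570 genes were called (707 higher, 863 lower), and without the 2 extreme libraries 1293 (551 higher, 742 lower), where the shares lower were 55.0% and 57.4% against 64.8%. Leaving out 1 sample gave 419, 874 and 554 called genes without control replicates 2, 3 and 4. Without TGF-β replicates 2, 3 and 4 there were 489, 463 and 618. These fits, with fewer samples, gave 137 to 358 higher, 271 to 516 lower, and 108 to 154 changed at least 2-fold. All 937 called genes kept their direction wherever they were tested. In the main fit the groups did not overlap for any of these genes, the 118 named ones included. Leaving out samples therefore could not reverse them, and their kept direction in those fits says nothing on robustness. The list calls fell from 21 to 0 with an estimated correlation, and leaving out 1 sample gave 19 to 23. They numbered 25 with the leukocyte score as a covariate and 25 without the 2 extreme libraries, and 12 of the 16 lists not called gained a call in at least 1 alternative, among them extracellular proteases and inhibitors with the replicate block (adjusted p = 0.0313). By fry 9 called lists lost their call. They were G1/S (fry adjusted p = 0.140), G2/M (0.413), DNA repair (0.163), AP-1 (0.0937) and YAP-TEAD genes (0.0559). The rest were cholesterol (0.119), leukocyte (0.313), mitochondrially encoded (0.170) and ribosomal protein genes (0.163). In turn, 2 other lists gained a call by fry, extracellular proteases (0.0424) and p53 targets (0.0397). The cause of these differences was not tested beyond the construction named.

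Among named genes only those not called reversed. Of the lists called in the main fit or in the alternative, only the leukocyte markers reversed. Lists called in neither were not counted, such as the basal keratinocyte genes, which were higher by camera and lower by fry. With the leukocyte score as a covariate the log2 changes were -0.0598 for PDGFRB, -0.19 for ESAM, -0.0886 for ZEB2 and -0.12 for SMAD4. The camera adjusted p of the leukocyte list was then 0.981. That value was set by construction, because the score is the mean log2 level of the same markers. Without the 2 extreme libraries the log2 changes were -0.0086 for HLA-C, -0.0105 for PDGFRB, -0.21 for ESAM, -0.0032 for CD74, -0.11 for ZEB2 and -0.16 for SMAD4. The camera adjusted p of the leukocyte list was 0.741 in that fit, whose left-out libraries were picked by these markers. Leaving out 1 sample moved COL15A1 from -0.89 to 0.18, LUM from -0.56 to 0.37 and TEK from -0.83 to 0.13, each with group means of 10.4 to 16.2 normalized counts, where few reads limit the precision, and ESAM from -0.0210 to 0.55. Of 3952 values of 180 named genes under alternatives, 3697 kept direction and side of the threshold, 99 lost and 139 gained a call, and 17 reversed.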

Other observations

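All tests of this part but the count of splits were chosen after the values were seen. Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many called genes as the real split (937, limma), which is the real split itself, and the highest other split gave 1 gene. With 10 splits the share cannot go below 0.1, so the splits are too few for a share under 0.05. Each other split also mixes control and TGF-β samples within its groups. A treatment effect then adds to the spread within groups and lowers the count, so these counts are no measure of samples without treatment.

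Transcripts of blood cells were present in all 6 libraries of this epithelial line. A list of 35 markers of 7 blood lineages was used, of which 21 had been seen before it was written. The most abundant were the neutrophil markers CSF3R (mean 74972 normalized counts), FCGR3B (25519) and MNDA (19190). HBB of erythroid cells (19146) and GNLY of NK cells (17682) came next. RNA or reads from 1 source could give each lineage 1 ratio to the leukocyte score: the largest SD of a lineage minus the score was 0.0701 for the list, 0.104 with HBD and IGHM, which had been looked at and left off, and 0.141 for the 13 tested genes not seen before, against 0.411 for the score itself, and a limit of 0.103, set after values were seen, was met by the list alone, so whether there is 1 source stays open. TGF-β as the cause is argued against by the controls, whose lowest index was 0.583 (mean of all libraries = 1), and the score differed between groups by 0.404 (exact two-sided permutation p = 0.4, where 0.1 is the smallest the design allows). In all, 889 genes followed the index (r over 0.9 and an intercept under 10% of the mean) and held 1.12% to 2.67% of the values of a library. Of these genes 0 were called by limma. The index overlapped between the groups (1.10 in control replicate 4, 0.974 in TGF-β replicate 3), so a gene that follows it closely could hardly separate them. That 0 therefore cannot show that blood-cell RNA left the calls untouched. How many genes would pass the limits on r and intercept without a relation was not computed, and the markers that form the index were among the genes screened.

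SMAD4 reads may come largely from that blood-cell RNA. Its intercept on the leukocyte index, the level left without blood-cell RNA, was -15.2% of its mean (-19.5% to -10.4% leaving out 1 library), against 102% for SMAD2, 118% for SMAD3 and 99.4% for TGFBR1. Over the 6 libraries r was 0.985 (exact permutation p = 0.0111, adjusted p = 0.0519 over 28 genes without the blood-cell markers) and Spearman's rho 0.829 (exact permutation p = 0.0583, adjusted p = 0.204), so neither passed after adjustment. Without the 2 libraries farthest from the median r was 0.675, where the range of the index is narrow and r of HBB also fell, from 0.986 to 0.744. The relation is thus shown mainly by those 2 libraries, and the drop cannot tell whether it is weak. A candidate explanation is loss of a chromosome 18 segment in these cells: the neighbours ME2 (48405419 to 48474691, hg19) and MEX3C (48700920 to 48744674) had intercepts of 7.58% (5.41% to 16.8% leaving out 1 library) and 1.56% (-4.22% to 21.8%), and ELAC1, whose span overlaps that of SMAD4 so that the pair may share reads, had -24.2% (-69.6% to 9.15%), while DNA copy number was not analysed here. For MEX3C r was -0.258 without the 2 farthest libraries, where the narrow range of the index limits what r can show. The next 4 protein-coding genes on either side with a mean of at least 30 normalized counts left 50.4% to 154%, with 105% for SKA1 and 87.0% for MBD2 nearest the segment, but CXXC1, next after SKA1, left 50.4% (41.5% to 63.9%, r = 0.946, and -0.113 without the 2 farthest libraries).

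The fall of interferon-stimulated genes was set against 2 technical explanations. Unequal blood-cell RNA is argued against by the median log2 change of the list, which was -0.39, and -0.50 with the leukocyte score as a covariate, with 38 members called lower where 24 had been. A single library is argued against by medians from -0.45 to -0.35 when 1 library was left out. A lower interferon response after TGF-β stays open as a hypothesis. The list and its test were fixed before the data were examined. The direction came from these data, and the 2 explanations were chosen and tested after they were seen.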
